A study of Sus scrofa with 37 samples.

How the data were processed

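The values were the TPM table deposited by the authors, 22630 genes by 37 libraries of FACS-purified pig islet cells, named by Ensembl gene identifiers. The submitters' processing notes credit the quantification to Salmon 0.11.3, and the labels give total RNA, a RecoverAll extraction kit, a SMARTer stranded total RNA kit (v2, Takara) and paired 75 bp reads on a NextSeq. Every column summed to 1e+06, so the sequencing depth of the libraries is unknown and no sampling error of a single value could be given. The raw reads were not used here, and the genome build and annotation release are not given in the sources used here. Gene symbols were those of the table (18624 genes). For 4006 identifiers without one, the symbol was looked up in an Ensembl name list, which named 168 of them. For 573 genes the 2 sources disagreed and the symbol of the table was kept. A symbol was shared by more than 1 identifier in 2625 genes, among them paralogs such as AMY2A, LSM5, CMC1 and UQCRH, whose values are uncertain; where a symbol was shared, the identifier with the highest mean TPM was used.

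The labels give cell type and age, and 12 groups were formed from them: beta cells at embryonic day E40 (6 libraries), E70 (5), E90 (2) and postnatal days P8 (2) and P22 (3); alpha cells at E40 (3), E70 (5), E90 (2), P8 (2) and P22 (2); delta cells at E90 (2) and P22 (3). Late fetal was the mean of E70 and E90 and neonatal the mean of P8 and P22, each age with equal weight. Expression was log2(TPM + 1). Genes with a TPM of at least 1 in at least 2 libraries (17839) were fitted with limma, 1 mean per group, and moderated with eBayes(trend=TRUE) on 25 residual degrees of freedom; 9 contrasts were tested, each with the Benjamini-Hochberg adjustment over all genes, and a gene was called below 0.05. The contrasts were beta against alpha cells over the 5 ages, late fetal against E40 and neonatal against late fetal in beta and in alpha cells, the 2 differences of those changes between beta and alpha cells (interactions), P22 against E90 in delta cells, and delta cells against the mean of beta and alpha cells at E90 and P22. Errors beside log2 folds are standard errors of the moderated fit and errors beside TPM are SD between libraries.

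Groups of genes were tested with camera at a preset correlation between genes of 0.01 and, for comparison, with a correlation estimated for each list, with the Benjamini-Hochberg adjustment over the lists within a contrast. The 27 lists were beta cell markers, alpha cell markers, delta cell markers, other islet hormones, endocrine progenitor factors, islet transcription factors, cell division genes, cell cycle inhibitors and cyclin D kinases, hormone secretion machinery, glucose sensing and glycolysis, mitochondrial respiration, genes normally low in mature beta cells, fetal growth genes, hormone and growth factor receptors, monogenic diabetes genes, the unfolded protein response, dissociation and early response genes, interferon response and antigen presentation, cytosolic ribosomal proteins, Notch, Wnt, Hedgehog and BMP pathway genes, acinar markers, duct markers, mesenchyme markers, endothelial markers, immune cell markers, neural and Schwann cell markers, and red blood cell markers. Listed genes that the table does not name included AMY2, CCNA2, CELA1, CELA3B, CLDN5, CTRB1, CUZD1, FFAR1, H19, HBA, HMGA2, HSPA1B, JUND, KCNJ11, KRT19, MEG3, NPW, OAS1, PRSS1, RPS19, SLC2A1, SLC2A3 and UNC13A. Counts of list members are given over all genes and adjusted over the list alone.

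The comparisons, tests, lists, alternatives and rule for named genes were chosen before the data were examined. The rule took, per comparison, the 8 largest called rises and falls with a mean TPM of at least 10 on the higher side, up to 4 members of each list by adjusted p, the islet hormones and the islet transcription factors, and for the interactions the 5 largest each way with the hormones; which of the eligible genes appear in the text was decided with the values in view, and a few of them are not reported here. The alternatives were a pseudocount of 0.1, no filter, a filter of TPM 5 in 3 libraries, scaling by the median of ratios over the 11622 genes above 0 in every library, quantile normalization, removal of hormone and mitochondrial genes, array weights, a fit with only the groups of a contrast, a block joining beta and alpha libraries whose title numbers differ by at most 2, 3 stages as groups, E70 and P22 alone, removal of title numbers under 100, and leaving out each library in turn. Alternatives added after the data were seen were a covariate for the level of Y-linked transcripts and a fit without 3 libraries that stood apart. Each contrast except P22 against E90 in delta cells was also compared with 100 splits of the same libraries, the real one included.

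The procedure was tested on simulated data, with noise independent between genes and, for a gene, of the same spread in all libraries. Changed genes were drawn from the more abundant ones. With no true change 0 genes were called. With 200 changed genes among 17839 it recovered 91.5%, 99% and 100% at log2 changes of 1, 2 and 4 between beta and alpha cells, 15.5%, 71.5% and 99% in the fetal interaction, and 20.5%, 81.5% and 97.5% between the delta groups, with 14, 16 and 16, 0, 2 and 3, and 4, 8 and 9 false calls; camera called the moved list and 0 of 100 random lists. The simulated lists had no correlation between genes, so they do not test camera on genes that move together. Real delta libraries were less alike than the others, with mean correlations within groups of 0.878 at E90 and 0.831 at P22. The lowest such mean elsewhere was 0.908, in alpha cells at E40. The simulated recovery and false calls may therefore not hold for the delta comparisons. The p-values measure the spread between these libraries, since the labels do not state whether they come from separate animals. The analysis used R 4.3.3 with limma 3.58.1, the packages data.table (1.17.8) and jsonlite (2.0.0), and Python 3.11.15 with matplotlib 3.10.9 and numpy 2.4.6. Coordinates were used only for the gene spans of the matched sets, and single-exon values and isoforms were not analysed here.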

Results

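The 37 libraries came from purified pig beta (18), alpha (14) and delta (5) cells between E40 and P22. Between 11693 and 15337 genes reached 1 TPM, and 20.95% to 39.74% of the listed genes were at 0. The fewest genes (11693) were in alpha E40 replicate 1. INS (insulin, ENSSSCG00000033740.1) took 13.0 ± 2.27% of the TPM of beta cells at E40, 18.9 ± 3.41% at E70, 26.6 ± 0.191% at E90, 33.9 ± 2.70% at P8 and 28.6 ± 5.74% at P22. The 18 beta libraries (9.41% or more) stood above all 14 alpha libraries (0.605% or less). GCG (glucagon, ENSSSCG00000015895.3) took 18.5 ± 0.912% of alpha cells at E40, 7.81 ± 2.26% at E70, 7.07 ± 0.434% at E90, 9.90 ± 0.229% at P8 and 9.24 ± 0.338% at P22. No beta library exceeded 0.230%. SST (somatostatin, ENSSSCG00000033815.1) took 3.01 ± 0.337% of delta cells at E90 and 2.38 ± 1.04% at P22. The delta libraries at E90 also held 23211 ± 4025 TPM of INS and 2619 ± 562 TPM of GCG, against 3436 ± 2165 and 39.7 ± 12.1 TPM at P22. PPY (pancreatic polypeptide) was highest in alpha cells at P8, at 1760 ± 960 TPM. IAPP (amylin) and GHRL (ghrelin) were listed near 0 in all groups, with highest group means of 1.12 and 1.9 TPM in alpha cells at P8. Whether the annotation behind the table captures these 2 transcripts was not tested, so the values do not show that the genes were silent.

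**Figure D1:**
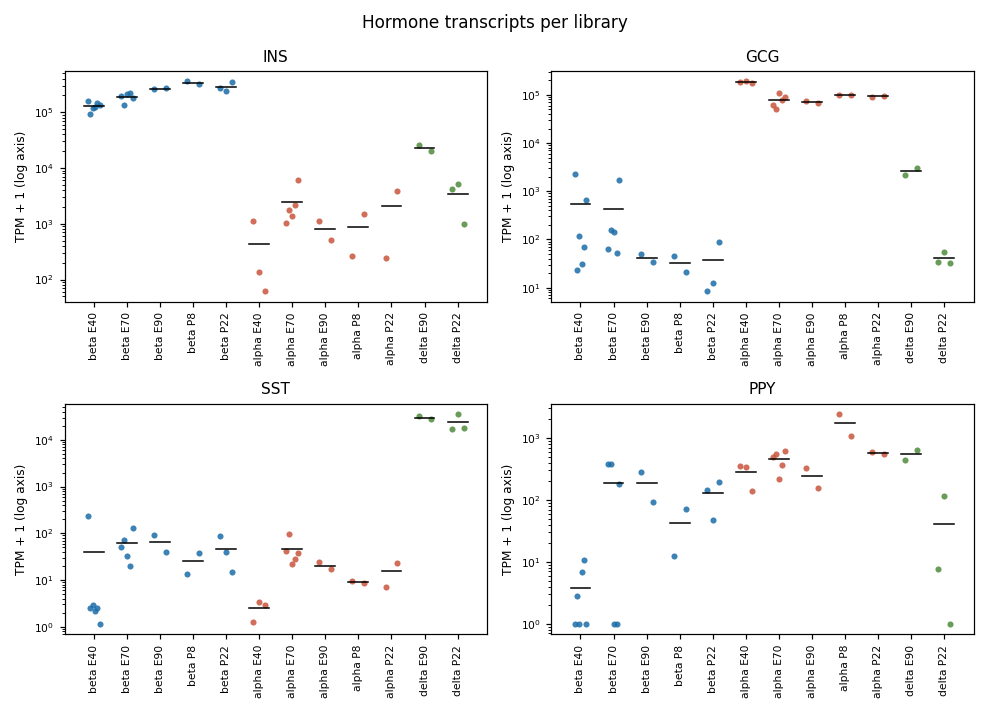
TPM of INS, GCG, SST and PPY in the 12 groups of sorted islet cells; points are libraries, bars are means and axes are log scales of TPM + 1. The highest group means of INS, GCG and SST were in beta, alpha and delta cells.

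Mitochondrially encoded transcripts took 13.2% of the TPM of beta cells at E40 and 6.85% at P22. In alpha cells they took 16.9% at E40, 10.3% at E90, 14.3% at P8 and 8.46% at P22. In delta cells they took 11% at E90 and 10.5% at P22. The shares of ribosomal protein transcripts at E40 and P22 were 5.99% and 2.43% in beta cells and 5.84% and 3.16% in alpha cells. At E90 and P22 they were 5.93% and 1.95% in delta cells. The 10 most abundant genes together held 25.9% of the TPM of beta cells at E40 and 52.5% at P8. In alpha cells they held 34.0% at E40, 25.1% at E90 and 38.2% at P8. In delta cells they held 18% at E90 and 32.4% at P22. The first 4 principal components of the libraries held 16.79%, 12.15%, 7.629% and 7.069% of the variance.

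Beta and alpha cells were compared over the 5 ages (18 against 14 libraries). INS was higher in beta cells by log2 8.29 ± 0.40 (adjusted p = 2.46e-16). GCG was lower there (log2 -10.72 ± 0.55; adjusted p = 8.87e-16). PCSK1 (ENSSSCG00000014169.3), the protease that starts the cleavage of proinsulin, was higher by 6.98 ± 0.16 (adjusted p = 3.06e-24). It was at 278 to 788 TPM in the beta groups and at most 8.54 TPM in the alpha groups. The secreted proteoglycan gene ESM1 (7.36 ± 0.29), the homeodomain gene HOPX (6.42 ± 0.31) and the glucose transporter gene SLC2A2 (4.48 ± 0.22) were higher in beta cells. The pancreatic transcription factor gene PDX1 (4.88 ± 0.22) and the fatty acid oxidation enzyme gene HADH (3.71 ± 0.12) were higher as well. The transcription factor genes IRX1 (-7.07 ± 0.29) and IRX2 (-5.60 ± 0.25), the lipid receptor gene GPR119 (-7.18 ± 0.27) and the oxytocin receptor gene OXTR (-5.37 ± 0.21) were lower in beta cells.

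Transcription factor genes lay on both sides of the comparison of beta with alpha cells. NKX6-1 (2.24 ± 0.17), MAFA (3.26 ± 0.27) and MNX1 (2.69 ± 0.32), which act in beta cell formation and insulin transcription, were higher in beta cells. The endocrine regulator RFX6 (-1.85 ± 0.10) and the ETS factor ETV1 (-4.33 ± 0.15) were lower. Among 32 measured islet transcription factors 10 were higher and 14 lower (11 and 14 adjusted over the list alone; camera adjusted p = 0.332). The thyroid hormone receptor gene THRB (3.33 ± 0.18), the glucagon receptor gene GCGR (3.27 ± 0.21) and G6PC2 (3.65 ± 0.28), which dephosphorylates glucose 6-phosphate, were higher in beta cells. The peptide hormone genes PPY (-3.83 ± 0.81) and PYY (-2.79 ± 0.36), the growth factor receptor gene FGFR1 (-2.72 ± 0.17) and the receptor tyrosine kinase genes RET (-2.35 ± 0.20) and ERBB3 (-2.36 ± 0.14) were lower. Of 40 genes considered for naming here, 28 had no overlap between the 18 beta and 14 alpha libraries. Large changes and small adjusted p in this comparison made genes eligible, so the count describes these genes and not the called genes at large. MAFA was above every alpha library in 12 of 18.

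Of 23 measured beta cell markers, 15 were higher and 1 was lower in beta cells (15 and 2 over the list alone; median log2 2.24, camera adjusted p = 1.07e-24, and 2.56e-08 with an estimated correlation). Alpha cell markers split 1 higher and 16 lower of 23 (2 and 16; median -1.24, adjusted p = 2.83e-15, and 0.000201 with an estimated correlation). The unfolded protein response followed with 17 of 25 higher and 0 lower (18 and 0; median 0.65, adjusted p = 9.17e-14, and 0.00297 with an estimated correlation). Examples were the chaperone gene HYOU1 (1.11 ± 0.10), the disulfide isomerase gene PDIA4 (1.37 ± 0.13) and the oxidase gene ERO1B (3.40 ± 0.14). Delta cell markers were 7 higher and 2 lower (8 and 2; adjusted p = 0.00839, and 0.0645 with an estimated correlation). Cell cycle inhibitors and cyclin D kinases were 6 and 0 of 18 (adjusted p = 0.00742, and 0.0645 with an estimated correlation), the growth inhibitor gene CDKN1C (1.63 ± 0.25) among them. Hormone secretion genes were 11 and 9 of 33 (13 and 10; adjusted p = 0.00675, and 0.473 with an estimated correlation). Examples were PCSK1 and the granule protein gene CHGB (1.97 ± 0.17). Cell division genes were 4 higher and 0 lower of 37 (adjusted p = 5.84e-05, and 0.439 with an estimated correlation), with the proliferation marker MKI67 at 0.87 ± 0.26 (adjusted p = 0.0149, and 0.0672 without alpha P22 replicate 1). Under median-of-ratios scaling 11 were higher. Mesenchyme markers were 3 and 0 of 19 (adjusted p = 7.82e-05, and 0.33 with an estimated correlation). Examples were the extracellular matrix genes FBN1 (3.58 ± 0.17) and FN1 (2.61 ± 0.16). Monogenic diabetes genes were 8 and 5 of 29 (adjusted p = 0.00839, and 0.232 with an estimated correlation). Endocrine progenitor factors were 3 and 7 of 19 (3 and 9; adjusted p = 0.0437, and 0.439 with an estimated correlation).

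Over all genes, 1166 were higher and 2581 lower in beta than in alpha cells, and 14092 did not pass (limma, adjusted p below 0.05). Scaling by the median of ratios moved the median of all genes by 0.131 and turned that split to 1795 higher and 1455 lower. With hormone and mitochondrial genes removed, the median moved by 0.159.

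Early to late fetal beta cells (6 libraries at E40, 7 at E70 and E90) gained MAFA and G6PC2 transcripts and lost IGF2BP1 and LIN28B transcripts. MAFA (ENSSSCG00000034820.1), an activator of insulin transcription, rose by log2 3.51 ± 0.40 (adjusted p = 5.33e-07). It went from 0.961 ± 1.62 TPM at E40 to 12.9 ± 3.28 at E70 and 23.3 ± 2.37 at E90. G6PC2 rose by 4.33 ± 0.42 (adjusted p = 3.03e-08). The homeodomain gene MEIS2 (3.0 ± 0.36), the granule zinc transporter gene SLC30A8 (1.17 ± 0.18) and the ferritin receptor gene SCARA5 (5.24 ± 0.41) rose too. So did the membrane-binding gene ANXA2 (4.31 ± 0.34), the muscarinic receptor gene CHRM3 (2.78 ± 0.38) and the neuronal enolase gene ENO2 (2.56 ± 0.37). The mRNA-binding gene IGF2BP1 (-3.17 ± 0.33; adjusted p = 1.02e-07) and the microRNA regulator LIN28B (-1.45 ± 0.27), both genes of fetal growth, fell. Falls were also seen for the retinoic acid binding gene CRABP2 (-4.31 ± 0.61), the pluripotency-associated gene ZFP42 (-3.44 ± 0.59) and the cartilage collagen gene COL2A1 (-3.79 ± 0.80). The endocrine transcription factor gene NEUROD1 (-1.24 ± 0.22) and the Notch ligand genes DLL1 (-1.83 ± 0.21) and JAG1 (-1.92 ± 0.37) fell as well. INS was at 0.80 ± 0.61 (adjusted p = 0.488) and did not pass, but 6 of 7 late fetal libraries were above every E40 library. PPY rose by 4.87 ± 1.22 (adjusted p = 0.00778, above every E40 library in 5 of 7). Its adjusted p was 0.064 without beta E90 replicate 1.

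Cell division genes fell most clearly in late fetal beta cells: 0 of 37 rose and 32 fell (0 and 35 over the list alone; median -1.63, adjusted p = 8.3e-27, and 0.02 with an estimated correlation). Examples were the replication helicase gene MCM7 (-0.85 ± 0.13) and the mitosis genes CDC20 (-1.70 ± 0.26) and HMMR (-1.72 ± 0.28). Mitochondrial respiration genes fell in 14 of 33 with 0 rising (0 and 16; median -0.52, adjusted p = 5.03e-09, and 0.02 with an estimated correlation), with the respiratory chain genes COX6C at -2.10 ± 0.31 and NDUFB8 at -1.44 ± 0.20. Dissociation and early response genes rose in 8 of 19 (9 and 0; median 1.25, adjusted p = 8.91e-06, and 0.242 with an estimated correlation). Examples were the heat shock gene HSPA1A (3.21 ± 0.57) and the immediate early gene EGR1 (3.04 ± 0.77; adjusted p = 0.00843, and 0.162 with E70 alone). Beta cell markers rose in 6 and fell in 2 (8 and 3; adjusted p = 0.0031, and 0.0545 with an estimated correlation). Alpha cell markers rose in 7 and fell in 1 (9 and 4; adjusted p = 0.0202, and 0.242 with an estimated correlation). Their median was -0.06, their mean 0.42 and the test upward, with a median of 0.31 under quantile normalization. Unfolded protein response genes fell in 10 and rose in 1 of 25 (1 and 12; median -0.52, adjusted p = 0.00129, and 0.242 with an estimated correlation), with the chaperone genes PDIA6 at -0.79 ± 0.16 and MANF at -1.17 ± 0.23. Under median-of-ratios scaling 6 of them fell, and under quantile normalization 3 fell and 2 rose (median -0.19). Under quantile normalization 5 of the mitochondrial respiration genes fell.

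In the same late fetal comparison, fetal growth genes fell in 6 and rose in 1 of 15 (adjusted p = 0.0099, and 0.242 with an estimated correlation), with the imprinted gene PEG10 at -1.62 ± 0.36 (adjusted p = 0.00245, and 0.0565 under quantile normalization). Notch, Wnt, Hedgehog and BMP pathway genes fell in 7 of 32 (1 and 9; adjusted p = 0.00268, and 0.347 with an estimated correlation). Ribosomal protein genes fell in 5 of 32 (median -0.32, turning to 0.11 under quantile normalization; adjusted p = 0.000101, and 0.494 with an estimated correlation). Glucose sensing and glycolysis genes rose in 4 and fell in 1 of 17 (adjusted p = 0.0218, and 0.242 with an estimated correlation). Genes normally low in mature beta cells fell in 1 of 13 (adjusted p = 0.0218, and 0.242 with an estimated correlation). Interferon response genes rose in 1 of 23 (adjusted p = 0.0341, and 0.594 with an estimated correlation). The hemoglobin genes HBB (-3.97 ± 0.88; adjusted p = 0.0026) and HBA2 (-3.52 ± 0.99; adjusted p = 0.0182, and 0.0542 without beta E40 replicate 1) carry oxygen in red cells and were highest at E40, with HBA2 at 157 ± 327 TPM. Beta E40 replicate 1 also held 2297 TPM of GCG and 230 TPM of SST. SST rose by 3.53 ± 0.80 (adjusted p = 0.0031), but 0 of 7 late fetal libraries stood above every E40 library, and the adjusted p was 0.055 with only the beta groups in the fit.

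From E40 to late fetal beta cells 704 genes rose, 1168 fell and 15967 did not pass. The majority turned to 1107 higher and 940 lower under quantile normalization, and to 952 and 833 with hormone and mitochondrial genes removed. The count of 1872 dropped to 1100 and 1050 without beta E90 replicates 1 and 2. Of 34 genes considered for naming, 22 had no overlap between the 7 late fetal and 6 E40 libraries. They were selected in this same comparison, so the count does not describe the called genes at large.

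Neonatal beta cell libraries (5 at P8 and P22) held more CPB1 and B2M and less CCND3 transcript than late fetal ones (7). CPB1 (ENSSSCG00000011694.3), a carboxypeptidase of acinar cells, rose by log2 8.30 ± 1.03 (adjusted p = 7.11e-06, above every late fetal library in 5 of 5). It reached 585 ± 382 TPM at P8 and 1142 ± 1374 at P22, where the libraries ranged from 37.1 to 2680 TPM. CPB1 was also higher after birth in alpha and delta libraries, and the source of this transcript was not tested. The acinar lipase genes PNLIPRP1 (6.0 ± 1.13) and PNLIP (5.03 ± 0.72) and the protease gene CTRC (4.86 ± 0.81) rose with it. The metal-binding gene MT1G rose by 6.0 ± 1.07. B2M, the light chain of MHC class I (2.25 ± 0.31), and the interferon-induced genes IFI6 (4.77 ± 0.83; adjusted p = 0.000341) and MX1 (1.95 ± 0.29) rose. MX1 was above every late fetal library in 3 of 5 and at 514 ± 398 TPM at P22 against 29.3 ± 4.69 at P8. The prolactin receptor gene PRLR rose by 1.10 ± 0.23. The activin receptor gene ACVR1C (-4.13 ± 0.53), the tachykinin gene TAC1 (-4.88 ± 0.68) and the microfibril gene MFAP2 (-3.38 ± 0.45) fell. So did the lectin gene LGALS2 (-4.36 ± 0.88), the ghrelin receptor gene GHSR (-2.03 ± 0.24), the peptidase gene DPP4 (-1.83 ± 0.23) and the cyclin gene CCND3 (-1.50 ± 0.15; adjusted p = 3.72e-07). INS was at 0.48 ± 0.64 (adjusted p = 0.756) and MAFA at 1.21 ± 0.43 (adjusted p = 0.0704), neither of which passed. Each was above every late fetal library in 4 of 5. MAFA passed under median-of-ratios scaling (adjusted p = 0.0301).

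Interferon response and antigen presentation genes rose in 8 of 23 in neonatal beta cells (16 and 0 over the list alone; median 1.22, adjusted p = 2.92e-22, and 0.0101 with an estimated correlation). Acinar markers rose in 8 of 17 (11 and 0; median 2.63, adjusted p = 4.17e-19, and 0.0525 with an estimated correlation). Ribosomal protein genes fell in 27 of 32 (0 and 30; median -0.87, adjusted p = 2.38e-17, and 0.119 with an estimated correlation). Examples were RPLP0 (-2.0 ± 0.26) and RPS4X (-1.17 ± 0.17), both parts of the cytosolic ribosome. Under median-of-ratios scaling 3 of them fell, with a median of -0.57. Mitochondrial respiration genes rose in 1 and fell in 11 of 33 (1 and 20; median -0.51, adjusted p = 9.08e-06, and 0.0712 with an estimated correlation), with the citrate synthase gene CS at -0.70 ± 0.14. None fell under median-of-ratios scaling, and CS no longer passed (adjusted p = 0.183). Glucose sensing and glycolysis genes fell in 5 of 17 (1 and 11; median -0.52, adjusted p = 0.00126, and 0.0935 with an estimated correlation), with the glycolytic enzyme genes GAPDH at -0.84 ± 0.14 (adjusted p = 0.0769 under median-of-ratios scaling) and PKM at -1.06 ± 0.19 (adjusted p = 0.0554 under quantile normalization). Under median-of-ratios scaling 1 of this list rose and 1 fell (median -0.24), and under quantile normalization 1 rose and 0 fell. Fetal growth genes fell in 7 of 15 (0 and 8; median -0.68, adjusted p = 0.00878, and 0.148 with an estimated correlation), with IGF2BP1 at -2.13 ± 0.35 and its relative IGF2BP2 at -1.10 ± 0.21. Of these, 2 fell under median-of-ratios scaling (median -0.39) and 2 under quantile normalization.

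Dissociation and early response genes had a median of 0.95 in neonatal against late fetal beta cells, with 0 of 19 passing (adjusted p = 1.58e-08, and 0.148 with an estimated correlation). Immune cell markers had a median of 0.27, with 0 of 17 passing (adjusted p = 0.0084, 0.369 with an estimated correlation and 0.0824 under median-of-ratios scaling). Unfolded protein response genes rose in 2 and fell in 1 of 25 (median 0.07, adjusted p = 0.00363, and 0.264 with an estimated correlation), HYOU1 among the risers at 0.74 ± 0.16. The transcription factor genes NEUROD1 (-0.77 ± 0.23; adjusted p = 0.0294) and ISL1 (-0.69 ± 0.20; adjusted p = 0.0239), both needed for endocrine cell development, and HNF4A (-0.85 ± 0.18), whose mutation causes a form of diabetes, fell. Under median-of-ratios scaling their adjusted p was 0.383, 0.252 and 0.096. Without beta P8 replicate 1 the adjusted p of NEUROD1 was 0.192 and that of ISL1 0.143.

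Between late fetal and neonatal beta cells 231 genes rose, 1502 fell and 16106 did not pass. Median-of-ratios scaling moved the median of all genes by 0.221 and gave 399 higher and 297 lower. The count of 1733 dropped to 847 and 917 without beta E90 replicates 1 and 2, and to 690 without beta P8 replicate 1.

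**Figure D2:**
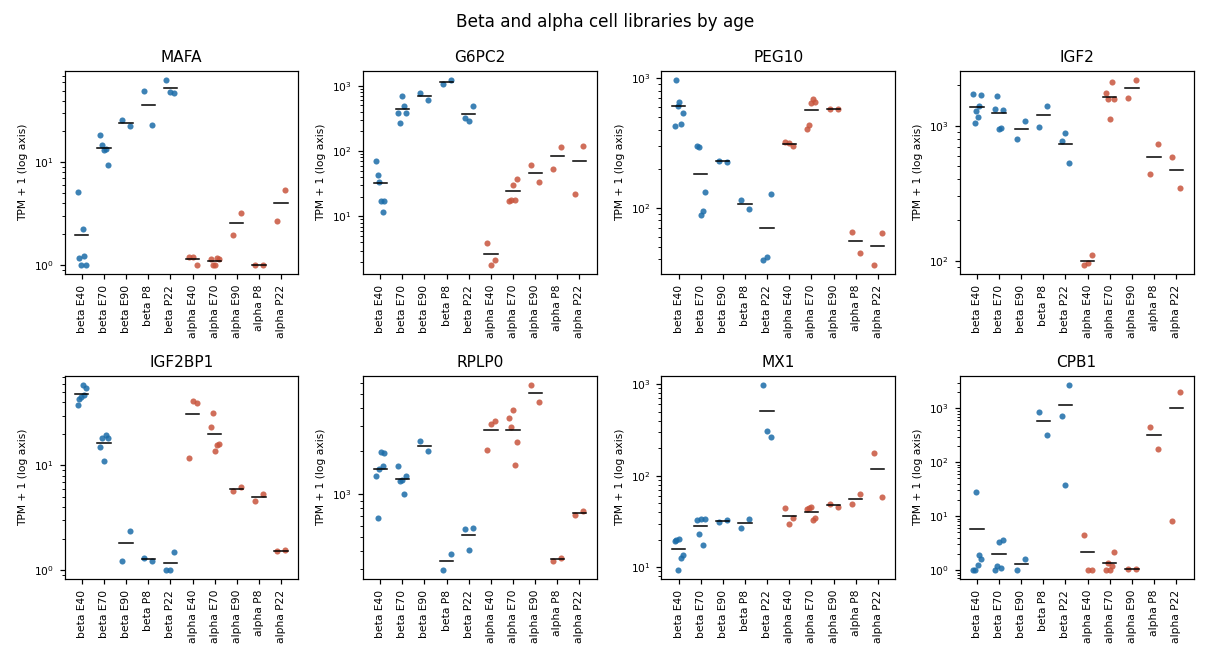
TPM of MAFA, G6PC2, PEG10, IGF2, IGF2BP1, RPLP0, MX1 and CPB1 in beta and alpha libraries by age; points are libraries, bars are means and axes are log scales of TPM + 1. CPB1 was spread over more than 1 order of magnitude between the P22 libraries of each cell type.

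From E40 (3 libraries) to late fetal ages (7) alpha cells gained IGF2 and PAPPA2 transcripts and lost FOXA1 transcripts. IGF2 (ENSSSCG00000035293.1), a fetal growth factor, rose by log2 4.11 ± 0.28 (adjusted p = 5.41e-11). It went from 99.2 ± 9.34 TPM at E40 to 1617 ± 348 at E70 and 1891 ± 396 at E90. PAPPA2, a protease of IGF-binding proteins, rose by 4.45 ± 0.30 (adjusted p = 5.41e-11). MEIS2 (3.82 ± 0.44), GATA6, a regulator of pancreas formation (3.04 ± 0.47), ANXA2 (4.61 ± 0.42) and SCARA5 (4.41 ± 0.50) rose. Further rises were those of the ependymin-related gene EPDR1 (4.71 ± 0.42), the chemokine gene CXCL12 (3.58 ± 0.59), the thyroid hormone receptor gene THRA (1.93 ± 0.24) and PKM (2.0 ± 0.21). The pioneer factor gene FOXA1 (-3.75 ± 0.37; adjusted p = 6.28e-08), LIN28B (-3.32 ± 0.33) and ZFP42 (-4.19 ± 0.71) fell. So did the vitamin D-binding protein gene GC (-3.31 ± 0.62) and the embryonic globin gene HBE1 (-2.99 ± 0.59). GCG was at -1.34 ± 1.01 (adjusted p = 0.381) and did not pass. Its mean was 184621 ± 9134 TPM at E40 and 78071 ± 22611 at E70, and all 7 late fetal libraries were below every E40 library. The error is estimated over all 12 groups. Among them are beta cells at E40, where GCG ranged from 21.9 to 2297 TPM. With only the alpha groups of this comparison in the fit, GCG did not pass either.

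Cell division genes fell in 21 of 37 in late fetal alpha cells with 0 rising (0 and 23 over the list alone; median -1.34, adjusted p = 5.86e-25, and 0.0549 with an estimated correlation). Examples were the kinetochore gene CENPF (-2.35 ± 0.50), the helicase gene MCM5 (-1.74 ± 0.32) and the condensin gene NCAPG (-1.94 ± 0.36). Beta cell markers rose in 11 and fell in 1 of 23 (median 0.81, adjusted p = 0.0119, and 0.113 with an estimated correlation). SLC30A8 (2.27 ± 0.23), the G protein regulator RGS16 (3.63 ± 0.37), G6PC2 (3.69 ± 0.51) and NKX6-1 (2.01 ± 0.32) rose. INS rose by 2.56 ± 0.74 (adjusted p = 0.0128, above every E40 library in 5 of 7). Its adjusted p was 0.0792 under median-of-ratios scaling, 0.0664 and 0.152 without alpha E40 replicates 2 and 3, and 0.0575 without alpha E90 replicate 1. Islet transcription factors rose in 13 and fell in 2 of 32 (18 and 2; median 0.79, adjusted p = 0.031, and 0.636 with an estimated correlation). Under median-of-ratios scaling 8 rose and 3 fell (median 0.42, adjusted p = 0.115). Hormone secretion genes rose in 16 and fell in 3 of 33 (22 and 3; median 0.67, adjusted p = 0.00923, and 0.636 with an estimated correlation), with the exocytosis gene CPLX2 at 1.40 ± 0.17. Under median-of-ratios scaling 5 of these rose and 4 fell (adjusted p = 0.341).

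Dissociation and early response genes rose in 11 of 19 in late fetal alpha cells (16 and 0; median 1.95, adjusted p = 0.00169, and 0.636 with an estimated correlation). Examples were HSPA1A (4.42 ± 0.69) and the immediate early genes FOSB (5.77 ± 1.29) and EGR1 (4.50 ± 0.94). Mitochondrial respiration genes rose in 1 and fell in 4 of 33 (median -0.10, adjusted p = 7.1e-05, and 0.113 with an estimated correlation), with COX6C at -2.35 ± 0.38. Of these, 9 fell under median-of-ratios scaling (median -0.57) and 7 under quantile normalization (-0.36). Ribosomal protein genes rose in 1 and fell in 5 of 32 (median -0.04, and -0.47 under median-of-ratios scaling; adjusted p = 0.000325, and 0.636 with an estimated correlation). Other islet hormones fell in 1 of 6 (median -0.01, adjusted p = 0.0293, and 0.301 with an estimated correlation). Mesenchyme markers rose in 1 and fell in 1 of 19 (median -0.02, adjusted p = 0.031, and 0.651 with an estimated correlation). Under median-of-ratios scaling the adjusted p of the hormones was 0.326 and that of the mesenchyme markers 0.341, and 7 dissociation genes rose. Alpha E40 replicate 1, with the fewest genes at 1 TPM of all libraries, is 1 of the 3 libraries on the early side.

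From E40 to late fetal alpha cells 3486 genes rose, 503 fell and 13850 did not pass. Of 33 genes considered for naming, 30 showed no overlap between the 7 and 3 libraries. Being selected in this same comparison, they do not describe the called genes at large. Median-of-ratios scaling moved the median of all genes by -0.322 and gave 1025 higher and 1214 lower. The count of 3989 dropped to 2351 without alpha E40 replicate 1 (1945 higher, 406 lower) and to 2539 without alpha E90 replicate 2.

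Neonatal alpha cells (4 libraries) held less PEG10 and IGF2 transcript than late fetal ones (7). PEG10 (ENSSSCG00000036049.1), an imprinted gene of retrotransposon origin, fell by log2 3.48 ± 0.40 (adjusted p = 3.23e-06, below every late fetal library in 4 of 4). It went from 569 ± 135 TPM at E70 to 54.2 ± 14.3 at P8. IGF2 (-1.77 ± 0.26; adjusted p = 6.72e-05), IGF2BP1 (-1.95 ± 0.37), the growth inhibitor gene CDKN1C (-2.11 ± 0.42) and FN1 (-2.27 ± 0.27) fell. So did the phosphate transporter gene SLC34A3 (-3.03 ± 0.26), the Hedgehog receptor gene PTCH1 (-1.21 ± 0.21) and the septin regulator CDC42EP5 (-3.63 ± 0.72). The transcription factor gene ASCL2 was listed at 0 in all 4 neonatal libraries, from 9.69 ± 5.62 TPM at E70. The endoplasmic reticulum gene WFS1 fell by 1.26 ± 0.28, with an adjusted p of 0.0506 without alpha P22 replicate 1. PRLR (1.34 ± 0.24; adjusted p = 0.00062) and the extracellular matrix gene MAMDC2 (3.98 ± 0.53) rose. RFX6 rose by 0.58 ± 0.16 (adjusted p = 0.0219), with an adjusted p of 0.189 without alpha P22 replicate 1. GCG was at 0.39 ± 0.92 (adjusted p = 0.884). With E70 and P22 alone, CDKN1C had an adjusted p of 0.111, and SCARA5, which fell by 2.85 ± 0.46, of 0.319.

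Ribosomal protein genes rose in 1 and fell in 23 of 32 in neonatal alpha cells (1 and 28 over the list alone; median -0.87, adjusted p = 3.48e-17, and 0.142 with an estimated correlation), with RPLP0 at -2.87 ± 0.28 (adjusted p = 1.29e-07) and RPS4X at -1.25 ± 0.18 (adjusted p = 0.0567 with E70 and P22 alone). Under median-of-ratios scaling 8 fell. Mitochondrial respiration genes fell in 13 of 33 (0 and 21; median -0.62, adjusted p = 1.11e-09, and 0.0165 with an estimated correlation), with the ATP synthase genes ATP5F1A at -1.23 ± 0.17 and ATP5F1B at -1.16 ± 0.17. Of the list 6 fell under median-of-ratios scaling. Glucose sensing and glycolysis genes fell in 5 of 17 (0 and 10; median -0.56, adjusted p = 0.000279, and 0.092 with an estimated correlation), with PKM at -1.50 ± 0.20 and GAPDH at -1.03 ± 0.15, and 3 falling under median-of-ratios scaling. Interferon response genes rose in 4 of 23 (10 and 1; median 0.92, adjusted p = 3.67e-09, and 0.142 with an estimated correlation), with IFI6 at 4.33 ± 0.87 and B2M at 1.71 ± 0.33, and 8 rising under median-of-ratios scaling and 7 under quantile normalization. The 2 alpha libraries of P22 lay far apart, at 27.3 and 2200 TPM of IFI6 and 112 and 542 TPM of B2M. Acinar markers rose in 4 of 17 (5 and 0; median 1.33, adjusted p = 3.02e-07, and 0.382 with an estimated correlation). CPB1 rose by 7.35 ± 1.09 (adjusted p = 7.55e-05). PNLIP was listed at 0 in all 7 late fetal libraries and reached 75.6 ± 101 TPM at P22. PNLIPRP1 rose by 4.90 ± 1.19 (adjusted p = 0.00878; 0.066 without alpha P8 replicate 1 and 0.113 without alpha P22 replicate 2). Dissociation and early response genes had a median of 0.63, with 0 of 19 passing (adjusted p = 0.00256, and 0.482 with an estimated correlation). Fetal growth genes fell in 4 of 15 and did not pass as a list (median -0.15, adjusted p = 0.0965).

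Between late fetal and neonatal alpha cells 213 genes rose, 1246 fell and 16380 did not pass. Median-of-ratios scaling moved the median by 0.112 and gave 414 higher and 487 lower. The count of 1459 dropped to 714 and 744 without alpha E90 replicates 1 and 2, to 762 without alpha P8 replicate 1 and to 868 without alpha P22 replicate 2.

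**Figure D3:**
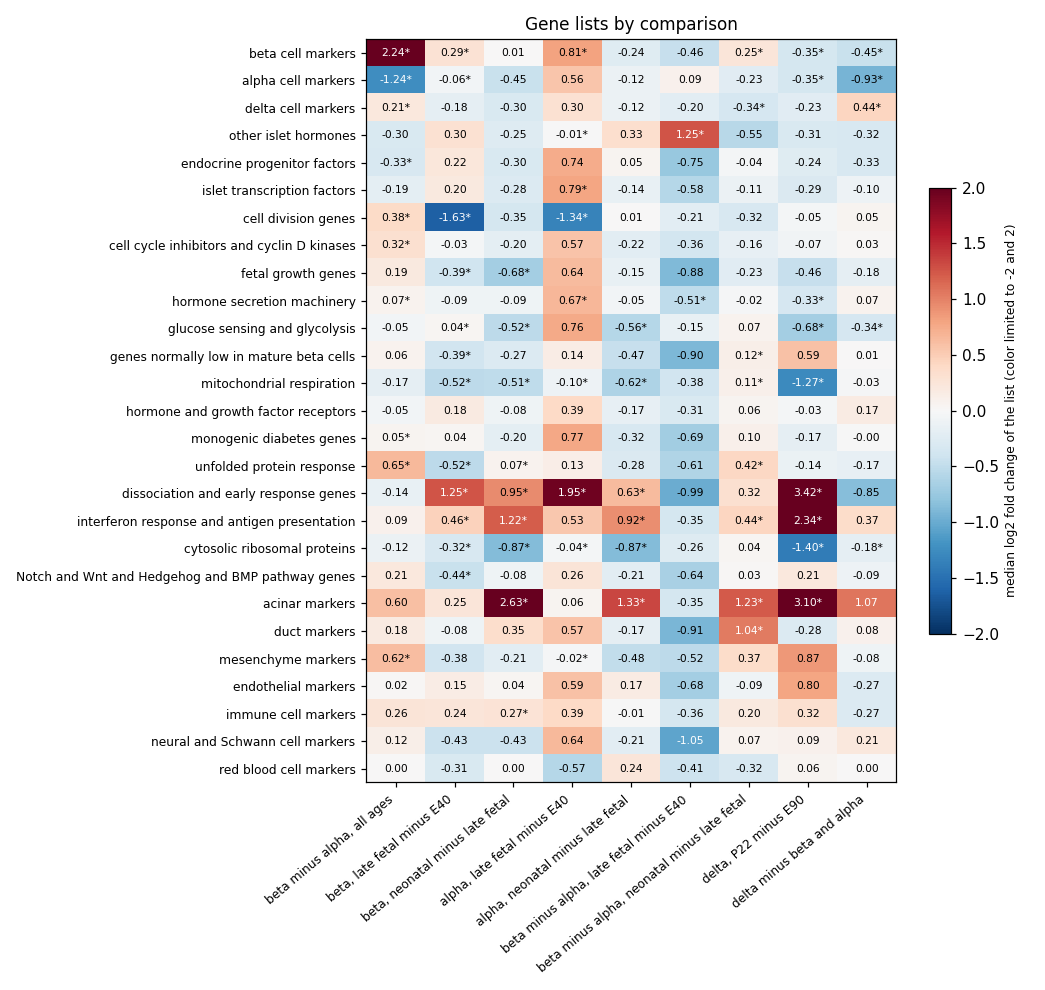
Median log2 fold of the members of 27 gene lists in the 9 comparisons; asterisks mark camera adjusted p below 0.05 at the preset correlation. Under quantile normalization the median of ribosomal genes from E40 to late fetal beta cells turned from -0.32 to 0.11.

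The fetal change of IGF2 and PCDH17 differed between beta and alpha cells by the interaction test. IGF2 had a lower beta than alpha change (log2 -4.47 ± 0.37; adjusted p = 8.87e-09). It was at 1376 ± 276 TPM in beta cells at E40 and 1232 ± 297 at E70, against 99.2 ± 9.34 and 1617 ± 348 in alpha cells. The adhesion gene PCDH17 (-5.26 ± 0.45; adjusted p = 9.33e-09), CXCL12 (-4.69 ± 0.77) and the sorting receptor gene SORCS1 (-4.01 ± 0.57) differed the same way, and FOXA1 (2.93 ± 0.48; adjusted p = 0.000445) the opposite way. MAFA (2.97 ± 0.64; adjusted p = 0.00643) and the gut and islet peptide gene PYY (3.85 ± 0.86; adjusted p = 0.00885) had larger beta changes but adjusted p of 0.0748 and 0.0698 with a pseudocount of 0.1. The opioid peptide gene PENK was at 4.21 ± 1.12 (adjusted p = 0.0253, and 0.0549 without alpha E40 replicate 1). NKX2-2 (-1.21 ± 0.26), NEUROD1 (-1.46 ± 0.34) and GATA6 (-2.52 ± 0.60), which act in pancreatic and endocrine development, passed. Under median-of-ratios scaling their adjusted p was 0.236, 0.286 and 0.0887. Without alpha E40 replicate 1 GATA6 was at 0.0535. INS (-1.76 ± 0.95; adjusted p = 0.277) and GCG (0.54 ± 1.31; adjusted p = 0.859) did not pass.

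In the fetal interaction, other islet hormones had 1 member with a higher beta change and 0 with a lower one of 6 (3 and 0 over the list alone; median 1.25, adjusted p = 0.0126, and 0.28 with an estimated correlation). Hormone secretion genes had 0 and 7 of 33 (1 and 14; median -0.51, adjusted p = 0.0345, and 0.913 with an estimated correlation). Under median-of-ratios scaling 1 was higher and 1 lower, the median was 0.00 and the adjusted p 0.709, while other islet hormones were at 0.0914. Over all genes 112 had a higher and 861 a lower beta change, and 16866 did not pass. Median-of-ratios scaling moved the median of all genes by 0.385 and gave 170 higher and 96 lower. The count of 973 dropped to 371 without alpha E40 replicate 1, 484 and 567 without beta E90 replicates 1 and 2, and 616 and 419 without alpha E90 replicates 1 and 2.

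The change around birth differed between beta and alpha cells for 36 genes, 13 with a higher and 23 with a lower beta change, and 17803 did not pass. The split was 28 and 24 under median-of-ratios scaling, 38 and 36 under quantile normalization, and 23 and 22 with hormone and mitochondrial genes removed. NSG2 (ENSSSCG00000016979.3), an endosomal protein of neurons, had a beta change higher than the alpha change by log2 3.21 ± 0.53 (adjusted p = 0.00361). It went from 25.1 ± 3.15 TPM at E90 to 60.7 ± 16.5 at P8 in beta cells and from 7.66 ± 0.196 to 2.14 ± 0.204 in alpha cells. The membrane skeleton gene SPTB (2.57 ± 0.48; adjusted p = 0.012, and 0.0535 without beta E90 replicate 1) and the procollagen protease gene ADAMTS2 (-2.31 ± 0.42; adjusted p = 0.012, 0.415 with a pseudocount of 0.1 and 0.0933 with E70 and P22 alone) passed as well. CDC42EP5 (4.93 ± 1.0), the sodium pump subunit gene FXYD2 (3.30 ± 0.69), the signaling gene SIPA1L2 (1.78 ± 0.38), the membrane gene LHFPL3 (-4.21 ± 0.91), the synuclein gene SNCB (-3.88 ± 0.79), the cell surface gene TMEM132D (-2.48 ± 0.51) and the potassium channel gene KCNJ3 (-2.48 ± 0.52) had adjusted p between 0.0222 and 0.0361. Each lost its call without 1 of several libraries. Without alpha E90 replicate 1 the adjusted p of LHFPL3 was 0.155 and that of SNCB 0.0799. Without beta P8 replicate 2 that of CDC42EP5 was 0.0846 and that of FXYD2 0.119. Without beta E90 replicate 2 TMEM132D was at 0.116 and KCNJ3 at 0.0892, and without beta E90 replicate 1 SIPA1L2 was at 0.125. The count of 36 dropped to 22 and 20 without beta E90 replicates 1 and 2, to 22 without beta P8 replicate 1 and to 20 without alpha E90 replicate 1.

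Several lists passed camera in the interaction around birth although none of their members were called. These were the unfolded protein response (median 0.42, adjusted p = 9.19e-07, and 0.122 with an estimated correlation), acinar markers (1.23, adjusted p = 0.00499, and 0.747 with an estimated correlation) and duct markers (1.04, adjusted p = 0.00499, and 0.362 with an estimated correlation). Interferon response genes (0.44, adjusted p = 0.00499, and 0.689 with an estimated correlation) and beta cell markers (0.25, adjusted p = 0.00836, and 0.122 with an estimated correlation) passed too. So did mitochondrial respiration genes (0.11, adjusted p = 0.0189, and 0.436 with an estimated correlation), delta cell markers (-0.34, adjusted p = 0.0192, and 0.156 with an estimated correlation) and genes normally low in mature beta cells (0.12, adjusted p = 0.0415, 0.362 with an estimated correlation and 0.101 under median-of-ratios scaling).

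Delta cells at P22 (3 libraries) were compared with those at E90 (2), and none of the genes named here passed with only these 5 libraries in the fit. IFI6 (ENSSSCG00000034570.1) was higher at P22 by log2 9.26 ± 1.22 (adjusted p = 2.72e-06), MX1 by 3.23 ± 0.42 and B2M by 2.71 ± 0.46, each with 3 of 3 P22 libraries above both E90 libraries. The heat shock genes HSPH1 (3.42 ± 0.49) and DNAJB1 (4.27 ± 0.67), and CPB1 (9.42 ± 1.52) were higher as well. So were the adaptor gene GRB10 (3.32 ± 0.68) and the glypican gene GPC5 (4.57 ± 0.58). CTRC, PNLIP, the immediate early gene EGR3 and the macrophage gene CD68 were listed at 0 in both E90 libraries and reached 314 ± 266, 184 ± 208, 161 ± 188 and 10 ± 6.08 TPM at P22. The respiration genes ATP5F1A (-2.61 ± 0.24; adjusted p = 1.6e-08), CS (-1.84 ± 0.20) and IDH3B (-3.33 ± 0.40) were lower at P22. So were the mitochondrial micropeptide gene MTLN (-5.87 ± 0.50; adjusted p = 5.24e-09) and the proton pump gene ATP6V1F (-5.64 ± 0.86). The ribosomal genes RPS4X (-2.23 ± 0.25) and RPL27 (-2.60 ± 0.30), and GAPDH (-2.07 ± 0.20) were lower. Among secretory and other genes, the prohormone processing gene CPE (-1.67 ± 0.24), the granule gene SCG2 (-2.30 ± 0.35), IGF2 (-2.06 ± 0.36), the lectin gene LGALS2 (-5.77 ± 1.30) and NKX2-2 (-1.54 ± 0.26) were lower at P22. GCG (-6.03 ± 1.29; adjusted p = 0.00091) and NKX6-1 (-1.58 ± 0.40) were lower. INS was lower (-3.05 ± 0.95; adjusted p = 0.017, and 0.0834 and 0.0736 without delta E90 replicates 1 and 2). PPY was lower too (-5.80 ± 1.90; adjusted p = 0.0236, and 0.134 without delta E90 replicate 2). SST was at -0.42 ± 1.24 (adjusted p = 0.899) and did not pass. GRB10 had an adjusted p of 0.123 without delta E90 replicate 2.

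The tests between the delta groups rest on the spread shared with the other 32 libraries. Mean correlations within groups were lower for delta cells than for the others, so these adjusted p may be too small. Between the delta ages 2304 genes were higher at P22, 2381 lower and 13154 did not pass. With only the 5 delta libraries in the fit 5 genes passed. The count of 4685 dropped to 2655 without delta E90 replicate 2 and to 1353 with array weights. Interferon response genes were higher in 19 of 23 (20 and 0 over the list alone; median 2.34, adjusted p = 1.83e-09, and 0.138 with an estimated correlation). Dissociation and early response genes were higher in 15 of 19 (16 and 0; median 3.42, adjusted p = 2.7e-09, and 0.156 with an estimated correlation) and acinar markers in 8 of 17 (9 and 0; median 3.10, adjusted p = 2.78e-05, and 0.429 with an estimated correlation). Ribosomal protein genes were higher in 1 and lower in 26 of 32 (1 and 29; median -1.40, adjusted p = 1.36e-15, and 0.156 with an estimated correlation). Mitochondrial respiration genes were lower in 21 of 33 (1 and 23; median -1.27, adjusted p = 2.37e-13, and 0.00266 with an estimated correlation). Glucose sensing and glycolysis genes were lower in 7 of 17 (median -0.68, adjusted p = 0.000381, and 0.113 with an estimated correlation) and beta cell markers in 9 of 23 (median -0.35, adjusted p = 0.0412, and 0.156 with an estimated correlation). Alpha cell markers were lower in 9 with 1 higher (median -0.35, adjusted p = 0.0412, and 0.429 with an estimated correlation) and hormone secretion genes in 11 with 3 higher of 33 (4 and 11; median -0.33, adjusted p = 0.0412, and 0.688 with an estimated correlation). Under median-of-ratios scaling the beta cell markers were at 0.0519 and the hormone secretion genes at 0.0642. Under quantile normalization 8 of the latter were higher and 6 lower.

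**Figure D4:**
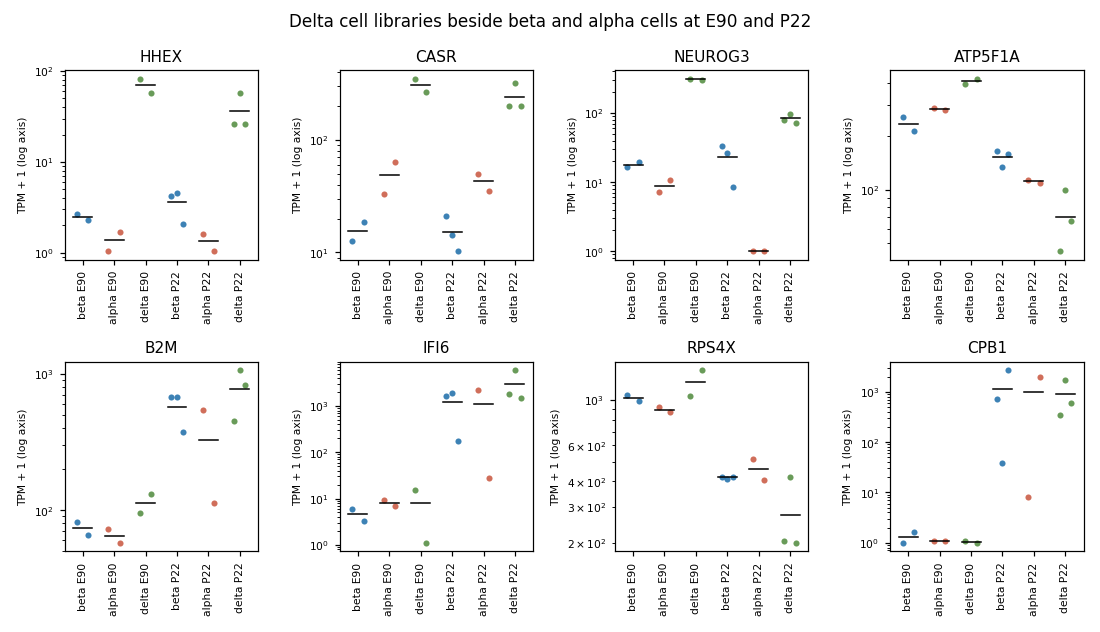
TPM of HHEX, CASR, NEUROG3, ATP5F1A, B2M, IFI6, RPS4X and CPB1 in beta, alpha and delta libraries at E90 and P22; points are libraries, bars are means and axes are log scales of TPM + 1. In delta cells NEUROG3 was at 307 ± 5.01 TPM at E90 and 82.5 ± 13.2 at P22.

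Delta cells (5 libraries) were compared with beta and alpha cells of the same 2 ages (9 libraries). The errors again use the spread shared by all libraries, which may be too small for delta cells. With array weights the count of 3625 dropped to 1770. At E90 cell type also went together with the level of Y-linked transcripts, described at the end. SST was higher by log2 9.88 ± 0.77 (adjusted p = 9.51e-11). HHEX (ENSSSCG00000036314.1), a transcription factor gene that maintains delta cells, was higher by 4.62 ± 0.33 (adjusted p = 1.51e-11). It was at 68.5 ± 17.8 TPM at E90 and 35.8 ± 18.4 at P22. The retinol carrier gene RBP4 (4.33 ± 0.22; adjusted p = 1.17e-14), the calcium-sensing receptor gene CASR (3.38 ± 0.26) and the potassium channel regulator gene ABCC9 (5.94 ± 0.30; adjusted p = 1.03e-14) were higher in delta cells. So were the angiotensin receptor gene AGTR1 (5.29 ± 0.38), the adhesion gene CHL1 (5.28 ± 0.38) and the sulfatase gene SULF2 (5.0 ± 0.33). The phospholipase gene PLCE1 (3.91 ± 0.22), FN1 (3.29 ± 0.24) and the lactate dehydrogenase gene LDHA (3.69 ± 0.48) were higher too. NEUROG3, the factor that starts the endocrine lineage, was higher by 4.43 ± 0.57 (adjusted p = 1.43e-06). ISL1 (1.87 ± 0.18), ETV1 (2.64 ± 0.23) and PDX1 (1.28 ± 0.32; adjusted p = 0.0051, and 0.054 with array weights) were higher as well. PCSK1 (3.81 ± 0.23), CHGB (2.44 ± 0.25), THRB (2.64 ± 0.26) and GCGR (2.62 ± 0.31) exceeded the mean of the beta and alpha levels. PDX1 was above every beta and alpha library in 0 of 5, PCSK1 and ETV1 in 2 and GCGR in 3.

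NKX6-1 (-2.37 ± 0.25), MNX1 (-2.88 ± 0.47), SLC30A8 (-2.58 ± 0.18) and the arginine transporter gene SLC7A2 (-3.06 ± 0.18) were lower in delta cells. So were the thyroxine carrier gene TTR (-2.76 ± 0.24) and the growth hormone receptor gene GHR (-2.68 ± 0.23). The dynein gene DYNC1I1 (-4.17 ± 0.45), the BTB-domain gene BTBD17 (-3.53 ± 0.34) and the thrombin inhibitor gene SERPIND1 (-3.63 ± 0.37, below every beta and alpha library in 0 of 5) were lower too. Delta cell markers were higher in 8 and lower in 0 of 23 (median 0.44, adjusted p = 5.07e-05, and 0.00581 with an estimated correlation). Alpha cell markers were higher in 3 and lower in 12 of 23 (4 and 12 over the list alone; median -0.93, adjusted p = 0.0003, and 0.128 with an estimated correlation). Beta cell markers were higher in 4 and lower in 8 of 23 (median -0.45, adjusted p = 0.0238, and 0.128 with an estimated correlation). Glucose sensing and glycolysis genes were higher in 2 and lower in 7 of 17 (2 and 8; median -0.34, adjusted p = 0.00514, and 0.128 with an estimated correlation). Ribosomal protein genes were higher in 1 and lower in 3 of 32 (median -0.18, adjusted p = 0.0238, and 0.837 with an estimated correlation). Under median-of-ratios scaling 0 were higher and 7 lower (median -0.42), and under quantile normalization 1 and 14 (median -0.52). Glycolysis genes were 0 and 10 under the first and 0 and 11 under the second. Over all genes 2434 were higher and 1191 lower in delta cells, and 14214 did not pass. Median-of-ratios scaling moved the median of all genes by -0.159 and gave 1263 higher and 1968 lower.

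Among the lists for other cell types, duct, endothelial, neural and Schwann cell and red blood cell markers passed camera in none of the comparisons except the duct list in the interaction around birth. In neonatal against late fetal beta cells, duct markers were at a median of 0.35 with 0 rising and 2 falling of 13 (adjusted p = 0.0926) and endothelial markers at 0.04 with 0 of 13 passing (adjusted p = 0.0531). Neural and Schwann cell markers were at -0.43 with 2 falling of 10 (adjusted p = 0.495) and red blood cell markers at 0.00 with 0 of 9 passing (adjusted p = 0.388). Immune cell markers were higher in 5 of 17 in delta cells at P22 (median 0.32, adjusted p = 0.0571).

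The sign of the median, the mean and the test differed for lists that were not called, such as glucose sensing, receptors and neural markers between beta and alpha cells, beta cell markers and hormone secretion genes in neonatal beta cells, and fetal growth genes in late fetal alpha cells.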

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

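Every test in this part and the thresholds it was read against were chosen after the result it bears on had been seen. The comparisons with other splits of the libraries were planned, but their reading was also written afterwards. For the ribosomal genes a second scaling test was added after the result of the first.

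Most of the genes that changed in alpha cells between E40 and late fetal ages rose. One explanation is that a few hormone and mitochondrial genes took a larger share of the TPM at E40, which lowers every other gene there. With those genes removed, 61.6% of the changed genes rose, below the 67% set as the limit for this explanation, which is in line with it for a large part of the excess. Another is alpha E40 replicate 1, which had the fewest genes detected; without it 82.7% rose, above the limit of 80%, so this library alone does not account for the excess.

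Ribosomal protein genes were lower after birth in beta, alpha and delta cells (27, 23 and 26 of 32 called). If a few abundant genes displaced them, calls should vanish under median-of-ratios scaling: 3 remained in beta and 8 in alpha cells, in line with displacement as part of the fall, and 24 in delta cells, which is not. Calls ended because the folds shrank while their errors grew: the list median went from -0.87 to -0.57 in beta cells (quartiles -0.946 and -0.765 before, -0.65 and -0.472 after; median error 0.230 before and 0.266 after) and from -0.87 to -0.70 in alpha cells (-1.06 and -0.686, then -0.89 and -0.513; 0.242 and 0.280). Displacement lowers all genes alike. In the added test the mean of the list per library stayed lower under that scaling by more than 2 times its standard error (-0.549 ± 0.216, -0.668 ± 0.227 and -1.33 ± 0.318). This argues against displacement as the whole of the fall in each cell type. It does so only if the median gene did not change, which the scaling assumes and which was not tested. A bias by gene span (start to end on the genome) or by level was tested with 1000 sets of other genes matched for both. These fell too, with a median of -0.449 in beta, -0.452 in alpha and -0.948 in delta cells. Such a bias therefore stays open as part of the fall. As far a fall was seen in 0 sets in beta cells and 0 in alpha cells, which argues against span and level as its only cause there. In delta cells 16 sets fell as far, so there it cannot be told. Span is not transcript length, so a bias against short transcripts was not tested. The sets were drawn gene by gene and do not carry any correlation among the ribosomal protein genes.

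The delta libraries at E90 held beta and alpha cell transcripts. If cells or RNA of the beta and alpha gates were mixed in, genes specific to those cells should be kept at no less than the share of the hormone itself. The lower quartile of 23 beta-specific genes was 13% of the beta E90 level, against 8.74% for INS. That of 42 alpha-specific genes was 8.38%, against 3.71% for GCG, and the medians were 18% and 20.8%. Under the hormone share were 2 of the beta-specific and 6 of the alpha-specific genes. Both quartiles met the prediction, but the genes were chosen between beta and alpha cells only. PCSK1 stood at 142% and ETV1 at 202%, which a mixture alone cannot give. Expression in delta cells themselves raises these shares, so the test cannot tell whether a mixture was present. NEUROG3 does not follow from a mixture, since the lowest delta E90 library held 304 TPM and the highest beta or alpha library of that age 18.3.

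Outliers were sought with Dixon's test in 24 groups of values, where chance gives about 1 in 20, and 6 were found. In alpha cells at E70, INS was 6045 TPM in replicate 5 (others 1048 to 2197) and SST 94.2 in replicate 2 (others 21.3 to 40.7). Beta E40 replicate 1 had 2297 TPM of GCG (others 21.9 to 665), 230 of SST (others 0.156 to 1.93) and 8.93% mitochondrial transcripts (others 13.4 to 14.8). In beta cells at E70, GCG was 1699 TPM in replicate 5 (others 52.2 to 160).

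The fetal change differed between beta and alpha cells by the interaction test for 973 genes, among them IGF2 (-4.47), PCDH17 (-5.26), CXCL12 (-4.69), SORCS1 (-4.01), PYY (3.85), PENK (4.21), FOXA1 (2.93), MAFA (2.97), NKX2-2 (-1.21), NEUROD1 (-1.46) and GATA6 (-2.52). The change around birth differed for 36 genes, among them CDC42EP5 (4.93), FXYD2 (3.30), NSG2 (3.21), SPTB (2.57), SIPA1L2 (1.78), LHFPL3 (-4.21), SNCB (-3.88), TMEM132D (-2.48), KCNJ3 (-2.48) and ADAMTS2 (-2.31).

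In 8 comparisons the count was set against 100 splits of the same libraries, the real one included. In each, 1 split reached the real number of called genes, the real one. This argues against chance as the source of the counts, as far as 100 splits can show. The splits treat the libraries as independent, which the labels do not state. They do not bear on how the counts depend on scaling. The highest of the other splits called 26 genes for beta against alpha cells (real 3747), 433 and 339 for the fetal and neonatal change of beta cells (1872 and 1733), 102 and 567 for those of alpha cells (3989 and 1459), 6 and 6 for the interactions (973 and 36) and 2319 for delta against the other cells (3625). For delta cells at P22 against E90 no splits were drawn, since 1 group has 2 libraries.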

How the results depend on the processing

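The Y-linked covariate, the fit without 3 libraries and the final rule for ties between pairs were chosen after the data were seen. Depth is unknown, groups hold 2 to 6 libraries, and the cause of the changes below was not tested unless stated. Directions held almost throughout for the genes considered for naming: of 249, 236 kept their direction and side of the threshold with a pseudocount of 0.1, 247 without a filter, 249 with the stricter filter, 236 with median-of-ratios scaling, 230 with quantile normalization, 240 with array weights, 211 with only the groups of the contrast (fewer libraries), 249 with the block, 247 with 3 stages and 240 without title numbers under 100; 224 of 231 did with hormone and mitochondrial genes removed, and 166 of 188 with E70 and P22 alone. Of the added alternatives, 241 kept it with the Y-linked covariate and 246 without 3 libraries. Large changes and small adjusted p in these same data made genes eligible for naming, so their stability says little about the other calls. The differences that turned were not called in the main analysis: under quantile normalization INS was at 0 in late fetal and 0 in neonatal beta cells (it is the top gene of each beta library, so its quantile is constant by construction), GCG at -0.88 in neonatal alpha cells and -0.30 in the fetal interaction; with the Y-linked covariate GCG was at -0.15 in neonatal alpha cells.

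Counts that moved by more than 1.5 times follow, in the order beta neonatal, alpha late fetal, alpha neonatal and fetal interaction: 696, 2239, 901 and 266 with median-of-ratios scaling; 856, 1805, 954 and 265 with quantile normalization, and 74 for the interaction around birth. With hormone and mitochondrial genes removed they were 861 (beta neonatal), 2219 (alpha late fetal) and 208 (fetal interaction). Array weights gave 5914 for beta against alpha cells, 5233 and 4221 for beta late fetal and neonatal, 7262 and 3195 for alpha late fetal and neonatal, 3328 and 208 for the interactions, 1353 for delta P22 against E90 and 1770 for delta against the other cells. With only the groups of the contrast the counts were 2696 (beta neonatal), 1721 and 92 (interactions), 5 (delta P22 against E90) and 2107 (delta against the other cells). The block gave 1666 and 93 for the interactions, E70 and P22 alone 488 (alpha neonatal) and 372 (fetal interaction), removal of title numbers under 100 gave 384 (fetal interaction), the Y-linked covariate 897 (alpha neonatal) and the fit without 3 libraries 526 and 65 (interactions). Among all genes called in the main analysis, many lost their call with median-of-ratios scaling. It kept 525 of 1733 calls for beta neonatal, 1526 of 3989 for alpha late fetal and 204 of 973 for the fetal interaction. Of 243 list tests 70 passed at the preset correlation, 66 with median-of-ratios scaling and 9 with estimated correlations. Median shifts of all genes under quantile normalization were 0.204 (beta neonatal), -0.337 (alpha late fetal), 0.111 (alpha neonatal) and 0.398 (fetal interaction).

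Leaving out 1 library at a time, where a lone remaining library is assumed to vary like the other groups, gave 3142 to 4110 genes for beta against alpha cells, 1050 to 2172 and 690 to 2070 for beta late fetal and neonatal, 2351 to 4464 and 714 to 1766 for alpha late fetal and neonatal, 371 to 1365 and 20 to 54 for the interactions, 2655 to 5518 for delta P22 against E90 and 2705 to 4484 for delta against the other cells. E70 and P22 alone gives no value of its own for comparisons it does not alter. Residuals of the 13 beta and alpha pairs with adjacent title numbers correlated at 0.0103 to 0.216 (median 0.126, 9 above 0.1), against -0.273 to 0.168 (median -0.0427) for 44 other combinations, and 12 beta and 11 alpha libraries of the pairs correlated best with their partner; 4 pairs did not exceed 0.1, so the pairing is a hint only.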

Other observations

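The comparison by Y-linked genes was chosen after the data were seen, and UCN3 and PAX4 were chosen after their values were seen. Further genes differed between beta and alpha cells over the 5 ages. The neuronal adhesion gene CNTNAP2 was higher in beta cells by log2 4.91 ± 0.26, at 74.1 ± 38.2 TPM at E40 and 24.4 ± 19 at P22 against at most 0.64 TPM in an alpha group, and the imprinted zinc finger gene PLAGL1 by 4.69 ± 0.24, at 106 ± 31.9 TPM at E40 and 47.1 ± 15.7 at P22. Both were also present in delta cells, at 88.1 ± 37.3 and 39.1 ± 31 TPM at P22. PDK4, a kinase that restrains pyruvate oxidation, was lower in beta cells (-4.81 ± 0.24); its alpha level was 239 ± 37.6 TPM at E40, 55.1 ± 20.2 at E70 and 464 ± 186 at P8. The gut peptide gene GUCA2A (-4.83 ± 0.38) was at 16.1 ± 17.5 TPM in alpha cells at E40 and 101 ± 11.1 at E90. UCN3, a peptide gene of mature beta cells, was already at 663 ± 98.3 TPM in beta cells at E40 and at 436 ± 70 at P22.

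PAPPA2 was at 6.17 ± 1.63 TPM in alpha cells at E40 and 533 ± 129 at P22, against 29.5 ± 13.1 and 121 ± 36.1 in beta cells. GHSR was at 181 ± 30.6 TPM in beta cells at E40 and 17.8 ± 2.26 at P22, and at most 5.4 in an alpha group. The inhibitor of prohormone processing PCSK1N rose in late fetal beta cells by 1.30 ± 0.20. PAX4, a factor of beta and delta cell formation, was highest in delta cells at E90, at 51.4 ± 45.3 TPM.

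The mean log2 level over 6 identifiers of 5 Y-linked genes (ZFY, USP9Y with 2, DDX3Y, KDM5D and EIF1AY) formed 2 sets of libraries, 1 between 0.808 and 1.35 and the other between 3.46 and 5.67. The low set held all 3 delta libraries of P22, both beta and both alpha libraries of E90, and 1 or 2 libraries of each beta and alpha group at E40, E70 and P22; the high set held the rest, with both delta libraries of E90 and all 4 libraries of P8. The level differed by at most 0.812 within the 13 beta and alpha pairs with adjacent title numbers. As a covariate it was associated with 17 genes, 6 of them the Y-linked identifiers that make it up. USP9Y, whose copy on the X chromosome is similar and whose value is therefore uncertain, was lower in delta cells at P22 (-5.88 ± 1.96, adjusted p = 0.0259). Its adjusted p with the covariate was 0.732, but USP9Y is part of the covariate, so this follows by construction. Since the 2 delta ages lay in different sets, age and Y-linked level cannot be told apart in delta cells. The same holds at E90 for delta cells (5.12 and 5.67) against beta and alpha cells (0.808 to 1.05). It also holds for E90 against P8 in beta and in alpha cells, the ages given for NSG2. All delta title numbers were higher than those of the beta and alpha libraries, so cell type cannot be separated from title order. The labels give no sex.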
